A study of Mus musculus with 12 samples.

How the data were processed

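Whole liver of mice aged 2 weeks was measured on 12 Affymetrix mouse Gene 1.0 ST arrays, 3 for each of 4 genotypes: floxed Stat3, Stat3Δhc, and both on an Mdr2 knockout. Total RNA was extracted and labelled with biotin. The log2 values were deposited by the authors after RMA, per the submitters' processing notes, which give no version. The values ran from 1.37 to 14.54. The labels do not state whether each array is a separate animal, and the 3 letters are taken as replicates.

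Samples were grouped by title. The source name field swaps the Mdr2-/- genotypes against title, description and genotype fields, and the Stat3 signal of each array followed the title. Grouping by source name was kept as an alternative.

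Of 35556 transcript clusters, 21789 name 1 gene, 1621 several and 12146 none in the annotation used. The 19938 genes with a cluster were each taken by the cluster of highest mean (999 genes had more than 1). A gene was tested if its value lay above the array's 40th percentile in at least 3 arrays, which left 13977. Each comparison used limma 3.58.1 (R 4.3.3) with lmFit and eBayes on all 12 arrays, 8 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. The prior had 4.82 degrees of freedom and an SD of 0.13. The median standard error was 0.11 for a comparison and 0.155 for the difference of the Stat3 effects. The 3 arrays per genotype limit the precision.

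The 5 comparisons were Stat3 deletion with and without the Mdr2 knockout, their difference, and Mdr2 loss in floxed and in Stat3Δhc liver. The 28 gene lists (493 genes, of which 417 were tested) were tested by camera with its correlation preset at 0.01, and with an estimated correlation and fry as alternatives. Genes named in the text were chosen by a rule: Stat3 and Abcb4, the 10 largest rises and falls with adjusted p under 0.05 and non-overlapping values per comparison (5 for the difference), and up to 4 passing members per list. Symbols that are placeholders were passed over. The groups, tests, lists, this rule and the first set of other settings below were fixed before the data were examined.

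The first set comprised no filter or a 60th percentile filter, the mean of a gene's clusters, all clusters, cyclic loess or median centring, trend and robust eBayes, array weights, only the compared groups, a block for the letter, groups by source name, and leaving out each array. The alternatives chosen after the data were seen were the pattern of Xist and Y-linked genes as a covariate, arrays of 1 pattern only, and leaving out X and Y genes. Arrays were put in the Xist or Y-linked pattern by their Xist, Eif2s3y, Kdm5d and Uty signals. Skeletal muscle, heart muscle and exocrine pancreas genes were also followed per array.

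On simulated data with 50 changed genes per fold, the test recovered 62, 90, 98 and 100 percent of genes changed 1.5-, 2-, 3- and 4-fold for Stat3 deletion on the knockout, with 9 false calls among 13777 unchanged genes. For the difference of the effects it recovered 36, 86, 96 and 96 percent, with 4 false calls. The camera test with its preset correlation found the 1 shifted list in both simulations, with 2 false calls among 27 unchanged lists for the former (adjusted p = 0.0199 and 0.0303, and 0.114 and 0.139 with an estimated correlation) and 0 for the latter. The simulated genes varied independently of each other, so this does not show how camera performs where the genes of a list vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe-level files and probe positions were not used here.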

Results

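Transcript levels were measured on microarrays in whole liver of mice aged 2 weeks, in 4 genotypes with 3 arrays each. The genotypes were floxed Stat3 (floxed), Stat3 deleted in the liver (Stat3Δhc), and both of these on an Mdr2 knockout. Mdr2 is encoded by Abcb4, the canalicular phospholipid transporter whose loss gives a mouse model of sclerosing cholangitis. Stat3 encodes a transcription factor that carries interleukin 6 and growth hormone signals. The array-wide median log2 signal lay between 6.01 and 6.14, and arrays of the same genotype correlated at 0.98 to 0.991. The number of arrays limits the precision, with a median standard error of 0.11 for a log2 change between genotypes.

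The targeted genes followed the sample titles in each of the 12 arrays. Stat3 lay between 9.19 and 9.54 on the log2 scale in the 6 floxed arrays and between 7.69 and 8.12 in the 6 Stat3Δhc arrays. It was 2.88-fold lower without the Mdr2 knockout (log2 change -1.52, SE 0.1, adjusted p = 1.08e-05) and 2.79-fold lower with it (-1.48, SE 0.1, adjusted p = 1.55e-05). Abcb4 lay between 10 and 10.28 in the 6 arrays without the knockout and between 8.87 and 9.36 in the 6 Mdr2-/- arrays. It was 1.97-fold lower in floxed liver (-0.98, SE 0.14, adjusted p = 0.000703) and 2.11-fold lower in Stat3Δhc liver (-1.08, SE 0.14, adjusted p = 0.000293). The files do not say which probes of either gene lie in the deleted part.

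Transcripts of sex and of other tissues also differed between the genotypes. The 6 arrays without the Mdr2 knockout and arrays B and C of Mdr2-/- Stat3Δhc liver had high Y-linked transcripts and low Xist, the transcript of the inactive X chromosome. The 3 Mdr2-/- floxed arrays and array A of Mdr2-/- Stat3Δhc liver had the opposite pattern. Among 33 skeletal muscle genes outside the ranked lists, 33 fell with Mdr2 loss in floxed liver (median log2 change -1.86) and 31 fell in Stat3Δhc liver (median -1.67). Their mean lay between 7.21 and 7.85 in the arrays without the knockout and between 5.48 and 5.78 in those with it. For 14 exocrine pancreas genes the mean spread from 5.63 to 9.77 in the arrays without the knockout and from 5.45 to 5.86 in those with it. In the fit, 0 of these pancreas genes passed the test in floxed liver and 1 fell in Stat3Δhc liver.

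**Figure D1:**
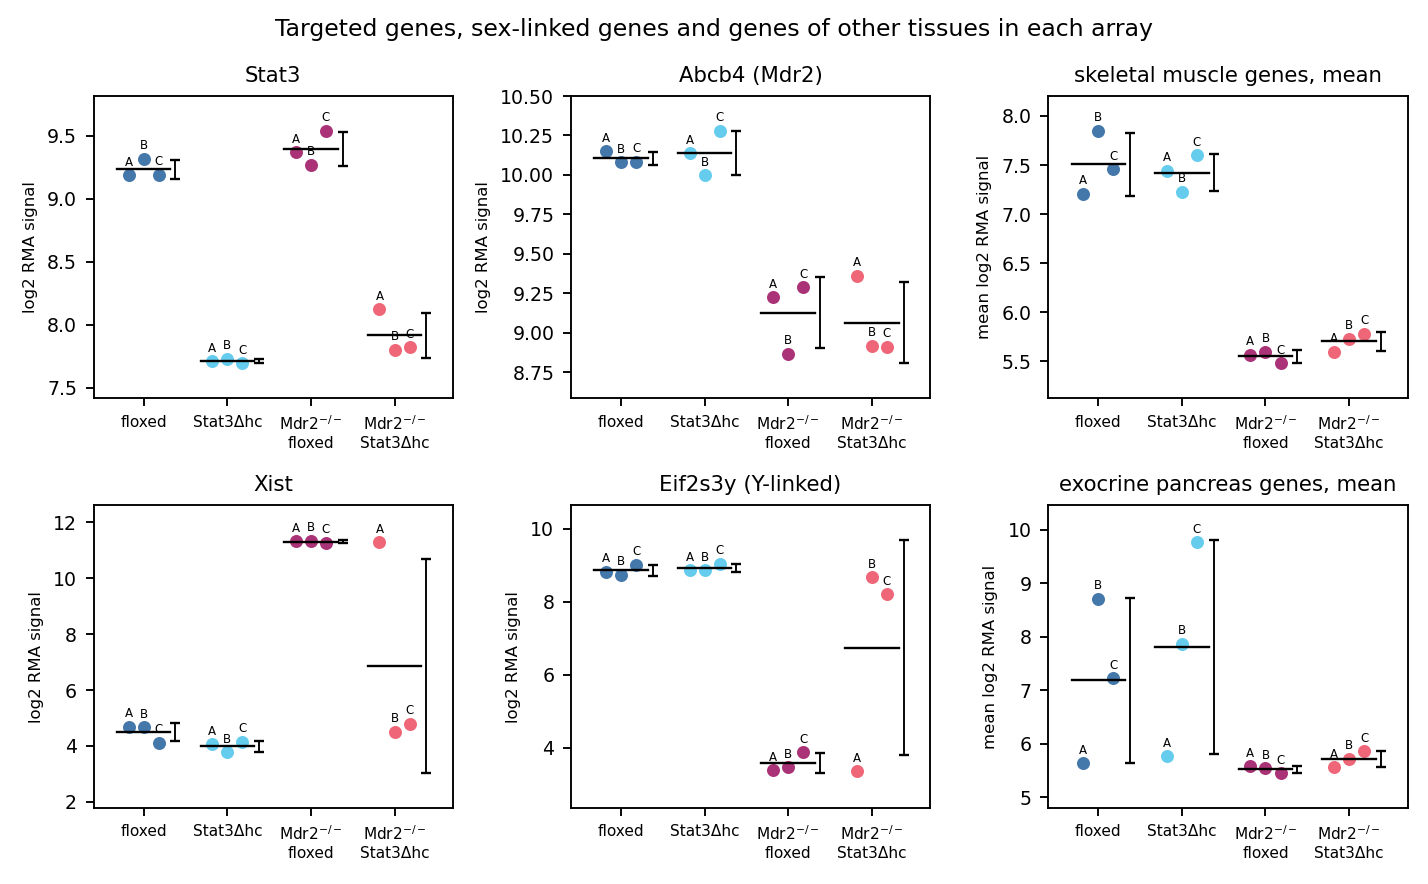
Log2 RMA signal of Stat3, Abcb4, Xist and the Y-linked gene Eif2s3y, and the mean log2 signal of skeletal muscle and exocrine pancreas genes, in each of the 12 arrays. Points are arrays with their letters, bars are group means and whiskers are 1 SD (n = 3), and array A of Mdr2-/- Stat3Δhc liver had an Xist signal of 11.3 where arrays B and C had 4.51 and 4.79.

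The first comparison, Stat3 deletion on the Mdr2 knockout, addresses which pathways change in the mice that develop cholestasis and bile acid injury. Fgl1, a hepatocyte-secreted protein of the fibrinogen family, fell 22.3-fold (log2 change -4.48, SE 0.21, adjusted p = 2.64e-07). The acute phase gene Saa2 fell by a log2 change of -3.68 (SE 0.48, adjusted p = 0.00185) to values under the lower quartile of each Mdr2-/- Stat3Δhc array, so that its fold is not given. Without array A of Mdr2-/- floxed liver its log2 change was -4.45 (adjusted p = 3.97e-06). The acute phase genes A2m and Lrg1 fell 3.93-fold (-1.97, SE 0.35, adjusted p = 0.0085) and 2.54-fold (-1.34, SE 0.22, adjusted p = 0.00526). Of 21 genes of the growth hormone axis list, which was not called (adjusted p = 0.593), 5 fell. Igfals, which encodes the subunit that stabilises circulating IGF1, fell 4.44-fold (-2.15, SE 0.17, adjusted p = 4.3e-05), and Igf1 itself fell 2.4-fold (-1.27, SE 0.1, adjusted p = 5.89e-05). Igfbp3 fell 2.46-fold (-1.3, SE 0.14, adjusted p = 0.000754) and the feedback inhibitor Socs2 fell 3.12-fold (-1.64, SE 0.33, adjusted p = 0.0139).

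The cytochrome P450 gene Cyp3a16 fell 4.22-fold (-2.08, SE 0.24, adjusted p = 0.000946) and the organic anion transporter gene Slc22a26 fell 4.6-fold (-2.2, SE 0.2, adjusted p = 0.000106). Prom1, a marker of progenitor and bile duct cells, fell 3.31-fold (-1.73, SE 0.2, adjusted p = 0.000946). The stellate cell genes Lrat and Reln fell by 0.93 (SE 0.14, adjusted p = 0.00426) and by 0.58 (SE 0.09, adjusted p = 0.00366) on the log2 scale. Among the rises, the trefoil factor gene Tff3 was 3.72-fold higher (1.9, SE 0.23, adjusted p = 0.00156) and Acmsd, an enzyme gene of tryptophan breakdown, was 2.97-fold higher (1.57, SE 0.3, adjusted p = 0.0107). The bile acid synthesis gene Acox2 rose by 0.55 (SE 0.1, adjusted p = 0.00903), the nuclear receptor gene Nr1i3 (CAR) rose by 0.75 (SE 0.14, adjusted p = 0.0101) and the hepatocyte gene Tdo2 rose by 1.14 (SE 0.17, adjusted p = 0.00376). Each gene given with an adjusted p under 0.05 in these paragraphs had 3 of 3 deleted arrays on the same side of the 3 floxed arrays. This held for 802 of all 806 called genes and 28.6 percent of all tested genes, so that it adds little to the call. By chance alone that share would be 0.1.

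By list, acute phase proteins were lower (9 of 22 fell and 0 rose, median log2 change -0.41, camera adjusted p = 2.04e-09), with 17 falls adjusted over the list alone. That call was lost with adjusted p = 0.345 with an estimated correlation. Cell cycle genes were lower (3 of 24 fell, adjusted p = 1.66e-07, 17 falls adjusted over the list alone), and so were endothelial markers (3 of 16 fell, adjusted p = 4.68e-05, 12 falls adjusted over the list alone). Bile acid synthesis genes were higher (5 of 13 rose and 1 fell, adjusted p = 0.0014, 8 rises and 1 fall adjusted over the list alone). Cholesterol synthesis genes were shifted up, with a median of 0.58 and adjusted p = 1.25e-05, although 0 of 19 passed the test (5 rises adjusted over the list alone). Msmo1 and Insig1 of this list had log2 changes of 1.54 (adjusted p = 0.0503) and 1.01 (adjusted p = 0.0606), and without array B of Mdr2-/- Stat3Δhc liver 0.91 and 0.64 (0.0913 and 0.152). They passed without array C of that group (0.012 and 0.0251) or A of floxed liver (0.0442 and 0.043), and Msmo1 also without A of Mdr2-/- Stat3Δhc liver (0.048). Both also passed with the stricter filter (0.0402 and 0.0487), cyclic loess (0.036 and 0.0416) and array weights (0.00193 and 0.00375). With array weights their log2 changes were 2.4 and 1.54. The interferon response list was higher with adjusted p = 0.00909 (2 of 21 rose, 2 adjusted over the list alone), as were hepatocyte markers with adjusted p = 0.0185 (2 of 14 rose, 4 adjusted over the list alone). Stellate cell markers were lower with adjusted p = 0.0484 (4 of 17 fell, 7 adjusted over the list alone). These 7 lists all had adjusted p = 0.702 with an estimated correlation. The stellate cell call was lost without array B of Stat3Δhc, C of floxed, A of Mdr2-/- floxed, or A or B of Mdr2-/- Stat3Δhc liver (adjusted p = 0.0526 to 0.115), and the hepatocyte call without array C of Mdr2-/- floxed (0.0998) or A of Mdr2-/- Stat3Δhc liver (0.0618). Both calls were also lost with cyclic loess (0.109 and 0.0747), and with no filter the hepatocyte (0.0593) and interferon (0.0787) calls were lost. The growth hormone list held 5 falls among 21 genes (3 rises and 7 falls adjusted over the list alone), with a median of 0.03, a mean of -0.27 and adjusted p = 0.593 for a downward shift.

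In all, 806 of 13977 genes changed, 261 up and 545 down, and 69 of them changed at least 2-fold (22 up and 47 down). With cyclic loess scaling the split was 466 up and 444 down. The count was 37 with the pattern of Xist and the Y-linked genes as a covariate, where Stat3, Fgl1, Tff3, Acmsd, Igfals, Slc22a26, Igfbp3 and Igf1 among the genes above kept their calls. Of those that lost them there, A2m, Saa2, Socs2, Reln, Cyp3a16, Prom1, Acox2, Nr1i3 and Tdo2 had log2 changes of -1.95, -3.42, -1.7, -0.58, -1.7, -1.54, 0.62, 0.79 and 1.14, and Lrg1 and Lrat had -0.93 and -0.58, while the median SE was 0.151 against 0.11. Only Mdr2-/- Stat3Δhc liver held both patterns (2 Y-linked arrays and 1 Xist array), so the covariate rests on its array A against arrays B and C. The log2 changes in that fit are those of array A against the 3 Mdr2-/- floxed arrays. The fit of the Xist arrays alone, 3 floxed against that single Stat3Δhc array, gives the same changes and is not a separate check. Traits of array A other than sex cannot be told apart from sex in either fit. Leaving out 1 array gave 302 without array B and 405 without array C of Mdr2-/- floxed liver, 1475, 351 and 466 without arrays A, B and C of Mdr2-/- Stat3Δhc liver, and 524 without array A of Stat3Δhc liver.

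**Figure D2:**
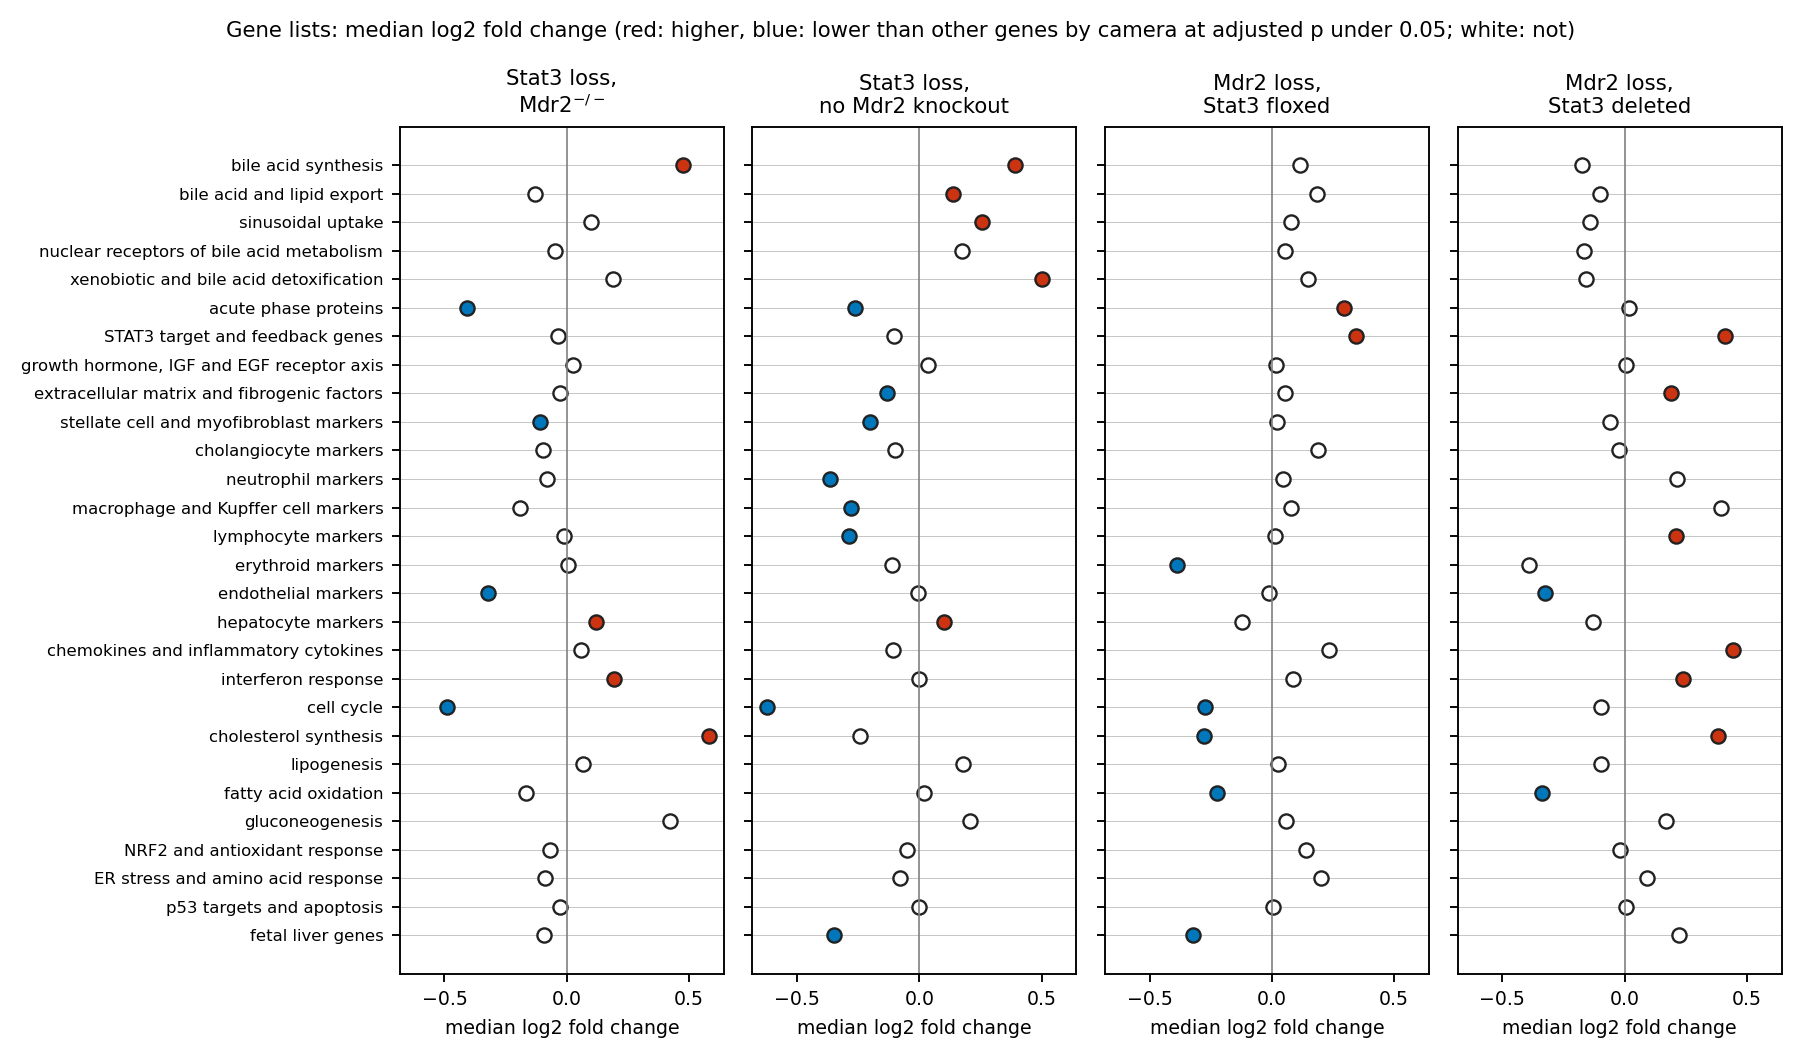
Median log2 fold change of the 28 gene lists (horizontal axis) in the 4 comparisons between genotypes. Each point is a list, filled where camera with its preset correlation called it higher (red) or lower (blue), and cell cycle genes had medians of -0.49 and -0.62 in the comparisons of Stat3 deletion.

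Stat3 deletion without the Mdr2 knockout shows the effect in mice that lack the cholestatic background. Cyp17a1, a steroid hydroxylase, rose 13.4-fold (log2 change 3.75, SE 0.34, adjusted p = 0.000151). The basolateral bile acid exporter Abcc3 rose 2.7-fold (1.43, SE 0.15, adjusted p = 0.000576). Among genes of bile acid synthesis or conjugation, Baat rose by 1.36 (SE 0.21, adjusted p = 0.00594), Cyp39a1 by 1.31 (SE 0.16, adjusted p = 0.00119) and Cyp27a1 by 1.11 (SE 0.14, adjusted p = 0.00162). The glutathione transferase gene Gstm1 rose by 1.11 (SE 0.16, adjusted p = 0.0035). The fetal liver genes Igf2 and Afp fell, Igf2 13.4-fold (-3.74, SE 0.3, adjusted p = 5.87e-05) and Afp 6.09-fold (-2.61, SE 0.41, adjusted p = 0.00686). Ces3a fell 6.24-fold (-2.64, SE 0.17, adjusted p = 1.08e-05), Prok1 6.91-fold (-2.79, SE 0.27, adjusted p = 0.000248) and Fgl1 5.74-fold (-2.52, SE 0.21, adjusted p = 5.97e-05).

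Of 21 genes of the growth hormone axis list, 3 fell here. Socs2 was 4.58-fold lower (-2.19, SE 0.33, adjusted p = 0.00492), Igfals 2.83-fold lower (-1.5, SE 0.17, adjusted p = 0.000793) and Igf1 lower by a log2 change of -0.82 (SE 0.1, adjusted p = 0.00161). With the mean of its clusters Socs2 had a log2 change of -1.57 (adjusted p = 0.00601). Of the acute phase genes, Apcs fell by 1.01 (SE 0.16, adjusted p = 0.00594) on the log2 scale. For each gene of these paragraphs 3 of 3 deleted arrays lay on the same side of the 3 floxed arrays. This held for 361 of all 361 called genes and 25.1 percent of all tested genes, so it adds little to the call. The list of this axis held 3 falls among 21 genes (1 rise and 5 falls adjusted over the list alone), with a median of 0.04, a mean of -0.28 and adjusted p = 0.0801 for a downward shift.

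Cell cycle genes were lower (8 of 24 fell, camera adjusted p = 5.08e-19), and 24 fell adjusted over the list alone. Xenobiotic and bile acid detoxification genes were higher (6 of 21 rose, adjusted p = 2.56e-09, 13 adjusted over the list alone), as were bile acid synthesis genes (4 of 13 rose, adjusted p = 3.89e-09, 7 adjusted over the list alone). Fetal liver genes were lower (3 of 12 fell, adjusted p = 1.29e-06, 7 adjusted over the list alone). Acute phase proteins were lower (3 of 22 fell, adjusted p = 6.12e-06, 3 rises and 12 falls adjusted over the list alone). Lymphocyte markers were lower with 0 of 11 past the test (adjusted p = 2.33e-05, 3 falls adjusted over the list alone). The bile acid and lipid export list was higher (1 of 11 rose, adjusted p = 0.0227, 1 adjusted over the list alone), a call lost without array A of floxed liver (0.0521). Each of these 7 lists had adjusted p = 0.171 with an estimated correlation. Lower lists also included extracellular matrix genes (3 of 27 fell, adjusted p = 0.000407, 3 adjusted over the list alone) and neutrophil markers (0 of 9 passed, adjusted p = 0.0037, 0 adjusted over the list alone). Hepatocyte markers (3 of 14 rose, adjusted p = 0.00269, 6 adjusted over the list alone) and sinusoidal uptake genes (2 of 7 rose, adjusted p = 0.02, 3 rises and 1 fall adjusted over the list alone) were higher. The uptake call was lost among the Y-linked arrays alone (0.0545), a fit that keeps all arrays of this comparison. These 4 lists had adjusted p = 0.338 with an estimated correlation. Macrophage markers (0 of 16 passed, adjusted p = 0.000441) were lower with adjusted p = 0.412 with an estimated correlation. Stellate cell markers (0 of 17 passed, adjusted p = 0.0164) were lower with adjusted p = 0.181 with an estimated correlation, and that call was lost without array B of floxed liver (0.0671). Adjusted over the list alone, 0 macrophage and 0 stellate cell markers passed.

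In all, 361 genes changed, 211 up and 150 down, and 59 of them at least 2-fold (25 up and 34 down). Leaving out 1 array gave 103, 131 and 134 without arrays A, B and C of Stat3Δhc liver, and 753, 76 and 69 without arrays A, B and C of floxed liver. The fit of the 8 arrays with the Y-linked pattern alone called 234. All arrays of this comparison have that pattern, so their log2 changes are the same there and only the estimated spread differs. That fit is therefore not a check on sex.

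**Figure D3:**
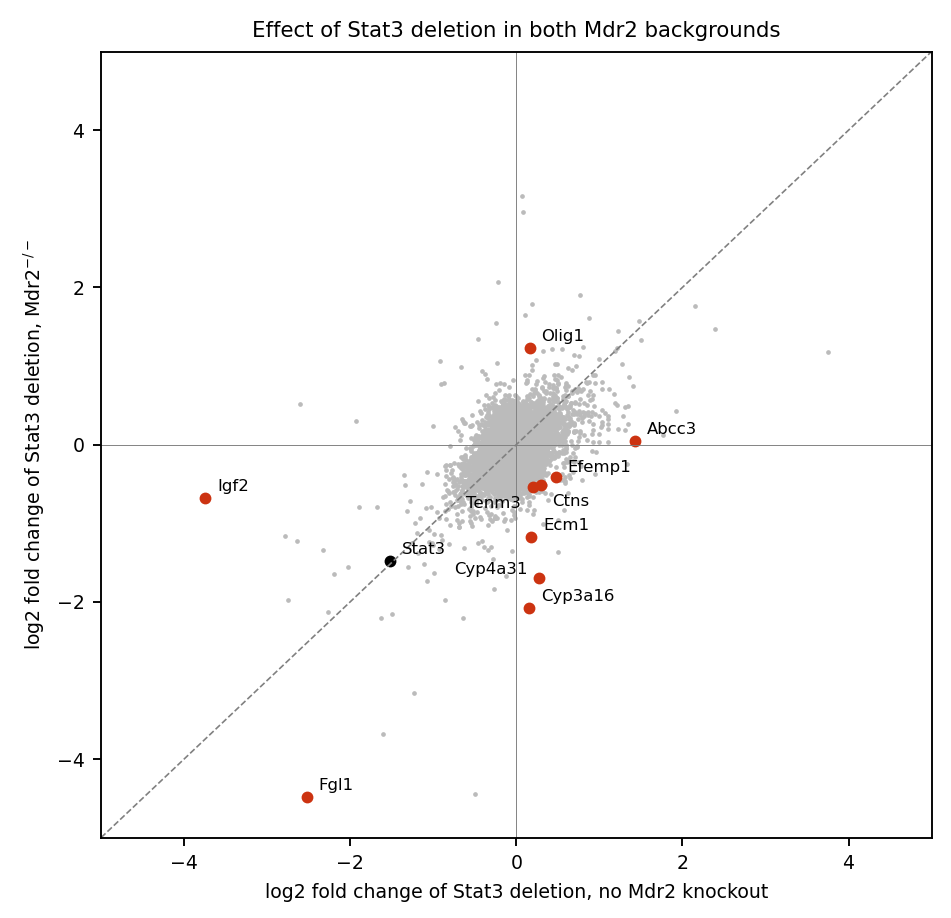
Log2 fold change of Stat3 deletion on the Mdr2 knockout (vertical axis) against that without it (horizontal axis) for 13977 genes, with the line of equal change. Red points are the 10 genes whose effects differed, such as Igf2 at -0.68 and -3.74, and the black point is Stat3 at -1.48 and -1.52.

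The test of the difference between these effects asks which responses to Stat3 deletion depend on the Mdr2 genotype. Fgl1 fell more on the Mdr2 knockout (difference -1.96, SE 0.29, adjusted p = 0.038). Cyp3a16 fell on the knockout and had a log2 change of 0.16 without it (difference -2.23, SE 0.34, adjusted p = 0.038). Ecm1, an extracellular matrix protein gene, had changes of -1.17 and 0.18 (difference -1.35, SE 0.2, adjusted p = 0.038), and Cyp4a31 had changes of -1.7 and 0.27 (difference -1.97, SE 0.31, adjusted p = 0.0387). The rise of Abcc3 without the knockout stood against a change of 0.05 on it (difference -1.38, SE 0.22, adjusted p = 0.0387). Igf2 fell without the knockout (-3.74) and did not pass on it (-0.68, adjusted p = 0.163), a difference of 3.06 (SE 0.43, adjusted p = 0.038). Olig1 had changes of 1.23 and 0.16 (difference 1.07, SE 0.14, adjusted p = 0.038). For Igfbp3 and Cxcl9 the differences were -0.92 (adjusted p = 0.126) and 1.81 (adjusted p = 0.136). They passed with the sex pattern as a covariate (-1.29 and 2.6, adjusted p = 0.0398 for both) and with array weights (-0.77 and 1.82, adjusted p = 0.0333 and 0.0185). The first 7 genes lost their calls without array A (adjusted p 0.0948 to 0.104) or B (0.0522 to 0.088) of Stat3Δhc, B (0.0856 to 0.14) or C (0.0795 to 0.157) of floxed, or B (0.0882 to 0.117) of Mdr2-/- Stat3Δhc liver. Some were also lost without Stat3Δhc C (Cyp3a16, Cyp4a31, Fgl1 and Ecm1, 0.0705 to 0.112), Mdr2-/- floxed A (Igf2, Cyp3a16, Cyp4a31, Abcc3 and Ecm1, 0.0528 to 0.0941), B (Cyp4a31 0.129, Fgl1 0.108) or C (Abcc3 0.0648), or Mdr2-/- Stat3Δhc C (Cyp3a16 0.0556, Fgl1 0.0516).

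By camera, 10 lists differed. Cholesterol synthesis genes were shifted up on the knockout (median difference 0.83, adjusted p = 1.35e-06), along with fetal liver genes (0.00197), lymphocyte markers (0.0086), interferon response genes (0.0124), and neutrophil markers and chemokines (both 0.0268). Endothelial markers (0.00117), detoxification genes (0.00327), and acute phase and fatty acid oxidation genes (both 0.0268) were shifted down. All 10 had adjusted p = 0.534 with an estimated correlation. Adjusted over all genes, the difference was positive for 1 fetal liver gene and negative for 1 detoxification gene. Adjusted over the list alone, it was positive for 3 fetal liver, 4 lymphocyte and 2 interferon genes and negative for 5 detoxification, 4 acute phase and 3 fatty acid oxidation genes, with 0 in the other 4 lists. Calls were lost without 1 array for neutrophil markers (Stat3Δhc A 0.0617, floxed C 0.0691, Mdr2-/- floxed A 0.144 and B 0.0933, Mdr2-/- Stat3Δhc A 0.137 and C 0.0581) and chemokines (floxed B 0.0659, Mdr2-/- floxed A 0.085 and B 0.0977, Mdr2-/- Stat3Δhc A 0.156). They were also lost for acute phase genes (floxed A 0.0526, Mdr2-/- Stat3Δhc B 0.0674 and C 0.0629), fatty acid oxidation genes (Stat3Δhc A 0.054, floxed A 0.0699, Mdr2-/- floxed A 0.18) and interferon response genes (floxed C 0.0556). With cyclic loess the lymphocyte (0.0548), neutrophil (0.198) and chemokine (0.0891) calls were lost, with no filter these (0.0729, 0.12 and 0.0567) and the interferon call (0.117), and with the sex pattern as a covariate the acute phase (0.313) and fatty acid oxidation (0.0762) calls.

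In all, 10 genes differed, 2 upward and 8 downward (4 and 7 with cyclic loess scaling), and 2360 had an unadjusted p under 0.05. Leaving out 1 array gave 0 without Stat3Δhc A or B, floxed C or Mdr2-/- Stat3Δhc B, 1 without floxed B, 3 without Stat3Δhc C or Mdr2-/- floxed A, 16 without Mdr2-/- Stat3Δhc C, 19 without Mdr2-/- floxed C, 47 without Mdr2-/- Stat3Δhc A and 64 without floxed A. With the sex pattern as a covariate, 6 genes differed and 0 of the 10 were among them, while Fgl1, Cyp3a16, Igf2, Olig1, Abcc3, Ecm1 and Cyp4a31 had differences of -2.16, -1.86, 3.28, 1.06, -1.27, -1.23 and -1.36 and the median SE was 0.184 against 0.155. Across genes, which are not independent replicates, the effects of Stat3 deletion in both backgrounds correlated with Pearson's r of 0.354 (jackknife SE 0.209) and Spearman's rho of 0.147. Of the genes changed in each background, 76 rose in both (3.94 for independent lists) and 58 fell in both (5.85), and 1 changed in opposite directions.

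Mdr2 loss in floxed liver was compared with Stat3 intact, where all 3 knockout arrays had the Xist pattern and all 3 others the Y-linked pattern, so that genotype and sex fall together. The sinusoidal uptake gene Slco1a1 rose by a log2 change of 5.15 (SE 0.35, adjusted p = 1.67e-06) from values under the lower quartile of each floxed array, so that its fold is not given. The cytochrome P450 gene Cyp2c39 rose 29.1-fold (4.86, SE 0.36, adjusted p = 3.5e-06). Lcn2, an acute phase gene that binds iron carriers, rose 6.51-fold (2.7, SE 0.32, adjusted p = 2e-04). Elovl7 rose 5.42-fold (2.44, SE 0.18, adjusted p = 3.85e-06), Plet1 5.13-fold (2.36, SE 0.19, adjusted p = 6.68e-06), Zbtb16 5.65-fold (2.5, SE 0.23, adjusted p = 2.1e-05) and the macrophage elastase gene Mmp12 4.38-fold (2.13, SE 0.27, adjusted p = 0.00034). The keratin genes Krt8 and Krt18, expressed in bile ducts and hepatocytes, rose by 0.98 (SE 0.14, adjusted p = 0.000841) and 1.13 (SE 0.18, adjusted p = 0.00173). Their list, the cholangiocyte markers, had a median of 0.19 and was not called. The export pump genes Abcb1b and Abcb1a rose by 1.26 (SE 0.16, adjusted p = 0.000269) and 0.65 (SE 0.1, adjusted p = 0.00146). These genes lie at places -1 and -2 from Abcb4 in the order of tested genes on chromosome 5. Their list held 4 rises and 2 falls among 11 genes (4 and 2 adjusted over the list alone) and was not called (adjusted p = 0.13, and adjusted p = 0.559 with an estimated correlation). The epoxide hydrolase gene Ephx1 rose by 1.25 (SE 0.11, adjusted p = 1.33e-05), the stress gene Atf3 by 1.15 (SE 0.18, adjusted p = 0.00125), the endotoxin receptor gene Cd14 by 1.45 (SE 0.25, adjusted p = 0.0027) and the chemokine gene Cxcl16 by 1.09 (SE 0.13, adjusted p = 0.000217).

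The falls beyond the Y-linked genes were led by skeletal muscle genes, such as Myh1, which reached values under the lower quartile of each knockout array (log2 change -5.6, SE 0.16, adjusted p = 6.41e-10), and Acta1, which fell 20.7-fold (-4.37, SE 0.2, adjusted p = 3.53e-08). Des of the stellate cell list, also a skeletal muscle gene, moved with them by -1.6 (SE 0.16, adjusted p = 4.71e-05). Acta2 of that list, the smooth muscle actin gene, changed by -0.87 (SE 0.18, adjusted p = 0.00665). Whether its fall is linked to that of the skeletal muscle genes was not tested. The heme synthesis gene Alas2 fell by 1.16 (SE 0.18, adjusted p = 0.00121), the imprinted growth inhibitor gene Cdkn1c by 1.02 (SE 0.15, adjusted p = 0.000804) and the lipogenic regulator Srebf1 by 0.86 (SE 0.13, adjusted p = 0.000951) on the log2 scale. For each gene of these paragraphs 3 of 3 Mdr2-/- arrays lay on the same side of the 3 arrays without the knockout. This held for 1767 of all 1785 called genes and 33.3 percent of all tested genes, so it adds little to the call.

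STAT3 target and feedback genes were higher (9 of 18 rose, camera adjusted p = 7.92e-06, 9 adjusted over the list alone), with Timp1 up by 1.74 (SE 0.27, adjusted p = 0.0015) and the receptor gene Osmr by 0.99 (SE 0.17, adjusted p = 0.00233). Erythroid markers were lower (3 of 8 fell, adjusted p = 0.018, 3 adjusted over the list alone), a call lost without array C of Mdr2-/- floxed liver (0.0619). Both lists had adjusted p = 0.239 with an estimated correlation. Acute phase proteins were higher (9 of 22 rose, adjusted p = 0.00061, 10 adjusted over the list alone), with adjusted p = 0.559 with an estimated correlation. Cell cycle genes (1 of 24 fell, adjusted p = 0.00061, 1 adjusted over the list alone) and cholesterol synthesis genes (1 of 19 fell, adjusted p = 0.0385, 1 adjusted over the list alone) were lower, both with adjusted p = 0.85 with an estimated correlation. The cholesterol call was lost with cyclic loess (0.0552) and without array A of floxed (0.261) or A (0.0587) or C (0.0706) of Mdr2-/- floxed liver. Fatty acid oxidation genes (4 of 18 fell and 1 rose, adjusted p = 0.018, 3 rises and 10 falls adjusted over the list alone) and fetal liver genes (3 of 12 fell, adjusted p = 0.0202, 4 adjusted over the list alone) were lower, both with adjusted p = 0.751 with an estimated correlation. The first of these calls was lost without array B of floxed (0.0533) or C of Mdr2-/- floxed liver (0.0683), and the second without B (0.0573) or C (0.0615) of floxed liver. With the sex pattern as a covariate, the acute phase (0.166), erythroid (0.0593), cell cycle (0.3) and cholesterol (0.618, now upward) calls were lost.

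In all, 1785 genes changed, 995 up and 790 down (673 and 888 after median centring), and 199 changed at least 2-fold (87 up and 112 down). The count was 102 with the sex pattern as a covariate, where Abcb4, Slco1a1, Cyp2c39, Zbtb16, Elovl7, Plet1, Ephx1, Cxcl16, Alas2, Myh1, Acta1 and Des among the genes above kept their calls and the median SE was 0.192. Among those that kept their calls, Slco1a1, Cyp2c39 and Elovl7 had log2 changes of 3.61, 3.41 and 1.84 with the covariate. These were smaller than the changes given above without it, so a kept call does not mean an unchanged size. Of the genes that lost their calls with the covariate, Lcn2, Mmp12, Krt8, Krt18, Abcb1b, Abcb1a, Atf3, Timp1, Cd14 and Osmr had log2 changes of 1.63, 1.75, 0.79, 0.85, 0.84, 0.42, 0.79, 1.07, 0.53 and 0.3, and Cdkn1c, Srebf1 and Acta2 had -0.84, -0.9 and -0.86. The count was 1117 and 1105 without arrays B and C of floxed liver and 1125 without array C of Mdr2-/- floxed liver.

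Mdr2 loss in Stat3Δhc liver was compared with Stat3 deleted, where 1 of the 3 knockout arrays had the Xist pattern. Cyp2c39 rose 23.3-fold (log2 change 4.54, SE 0.36, adjusted p = 6.16e-06) and Slco1a1, again from under the lower quartile, by a log2 change of 3.58 (SE 0.35, adjusted p = 4.08e-05). Plet1 rose 7.91-fold (2.98, SE 0.19, adjusted p = 9.18e-07), Lcn2 6.93-fold (2.79, SE 0.32, adjusted p = 0.000131) and Ubd, an interferon-inducible ubiquitin-like gene, 5.42-fold (2.44, SE 0.27, adjusted p = 0.000103). Igf2 rose 4.84-fold (2.28, SE 0.3, adjusted p = 0.000416) and Afp 3.3-fold (1.72, SE 0.41, adjusted p = 0.0138). The chemokine genes Cxcl10 and Cxcl9 rose 4.9-fold (2.29, SE 0.39, adjusted p = 0.00204) and 3.14-fold (1.65, SE 0.29, adjusted p = 0.00255). Krt18 rose by 1.49 (SE 0.18, adjusted p = 0.000219), the collagen gene Col1a1 by 0.8 (SE 0.12, adjusted p = 0.000886) and the connective tissue growth factor gene Ccn2 by 0.77 (SE 0.16, adjusted p = 0.00657). The cholangiocyte list, which holds Krt18, had a median of -0.023 and was not called. Cyp3a16 fell 7.31-fold (-2.87, SE 0.24, adjusted p = 9.37e-06), Igfbp3 2.84-fold (-1.51, SE 0.14, adjusted p = 3.37e-05) and Igfals 2.61-fold (-1.38, SE 0.17, adjusted p = 0.000216).

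The sterol exporters Abcg5 and Abcg8 had changes of -0.88 (SE 0.12, adjusted p = 0.000633) and -0.95 (SE 0.16, adjusted p = 0.00231), and Hsd3b7 of bile acid synthesis fell by 0.82 (SE 0.1, adjusted p = 0.000298). Skeletal muscle genes again led the falls, with Myh1 again under the lower quartile of the knockout arrays (-5.45, SE 0.16, adjusted p = 9.04e-10). Des moved with them by -1.61 (SE 0.16, adjusted p = 4.26e-05). Acta2 was lower as well (-1.15, SE 0.18, adjusted p = 0.00113). Pnliprp1, a pancreatic lipase gene, fell 9.56-fold (-3.26, SE 0.7, adjusted p = 0.00808), with log2 changes of -2.52 without array C and -4.05 without array A of Stat3Δhc liver and -1.87 with array weights. Its signal in arrays A, B and C of that group (7.82, 9.51 and 10.9) followed the means of the pancreas genes (5.77, 7.87 and 9.77). For each gene of these paragraphs 3 of 3 Mdr2-/- arrays lay on the same side of the 3 arrays without the knockout. This held for 2397 of all 2431 called genes and 37.2 percent of all tested genes, so it adds little to the call.

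STAT3 target and feedback genes were higher (10 of 18 rose, camera adjusted p = 3.77e-07, 12 adjusted over the list alone), with adjusted p = 0.283 with an estimated correlation. Fatty acid oxidation genes were lower (11 of 18 fell, adjusted p = 8.01e-05, 11 adjusted over the list alone), with Cyp4a14 at -1.45 (SE 0.24, adjusted p = 0.00163) and Pdk4 at -1.05 (SE 0.17, adjusted p = 0.00181). Neither this fall nor the one in floxed liver is assigned to hepatocytes, since skeletal muscle, whose transcripts fell in the same arrays (31 and 33 of 33 genes, medians -1.67 and -1.86), also expresses such genes as Pdk4. Chemokines were higher (7 of 16 rose, adjusted p = 0.000136, 9 rises and 1 fall adjusted over the list alone), as were interferon response genes (8 of 21 rose and 1 fell, adjusted p = 0.00018, 8 rises and 1 fall adjusted over the list alone). These 3 lists had adjusted p = 0.402 with an estimated correlation. Endothelial markers were lower (7 of 16 fell, adjusted p = 0.00108, 1 rise and 9 falls adjusted over the list alone), with adjusted p = 0.545 with an estimated correlation. Extracellular matrix genes were higher (9 of 27 rose and 2 fell, adjusted p = 0.00455, 10 rises and 2 falls adjusted over the list alone), with adjusted p = 0.695 with an estimated correlation. Cholesterol synthesis genes were higher (4 of 19 rose and 1 fell, adjusted p = 0.0101, 7 rises and 1 fall adjusted over the list alone), with adjusted p = 0.842 with an estimated correlation. Sqle, the squalene epoxidase gene, rose by 1.91 (SE 0.45, adjusted p = 0.0123), and by 1.17 (adjusted p = 0.00419) without array B of Mdr2-/- Stat3Δhc liver, where the list's call was lost (0.415). Lymphocyte markers were higher (4 of 11 rose, adjusted p = 0.0101, 5 adjusted over the list alone), with adjusted p = 0.532 with an estimated correlation and a call lost with cyclic loess (0.0682) or no filter (0.0769).

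In all, 2431 genes changed, 964 up and 1467 down (635 and 2052 after median centring), and 220 changed at least 2-fold (89 up and 131 down). Leaving out 1 array gave 1405 and 1156 without arrays A and C of Stat3Δhc liver and 1537 without array C of Mdr2-/- Stat3Δhc liver. Across genes, which are not independent replicates, the effects of Mdr2 loss in floxed and Stat3Δhc liver correlated with Pearson's r of 0.678 (jackknife SE 0.122) and Spearman's rho of 0.404. Of the genes changed in each, 403 rose in both (68.6 for independent lists), 491 fell in both (82.9), and 3 rose and 3 fell in the first against the opposite change in the second. The skeletal muscle genes, of which 33 and 31 of 33 fell (medians -1.86 and -1.67), are part of these correlations and shared falls. Neither was recomputed without them, so how far the likeness rests on muscle transcripts was not tested.

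**Figure D4:**
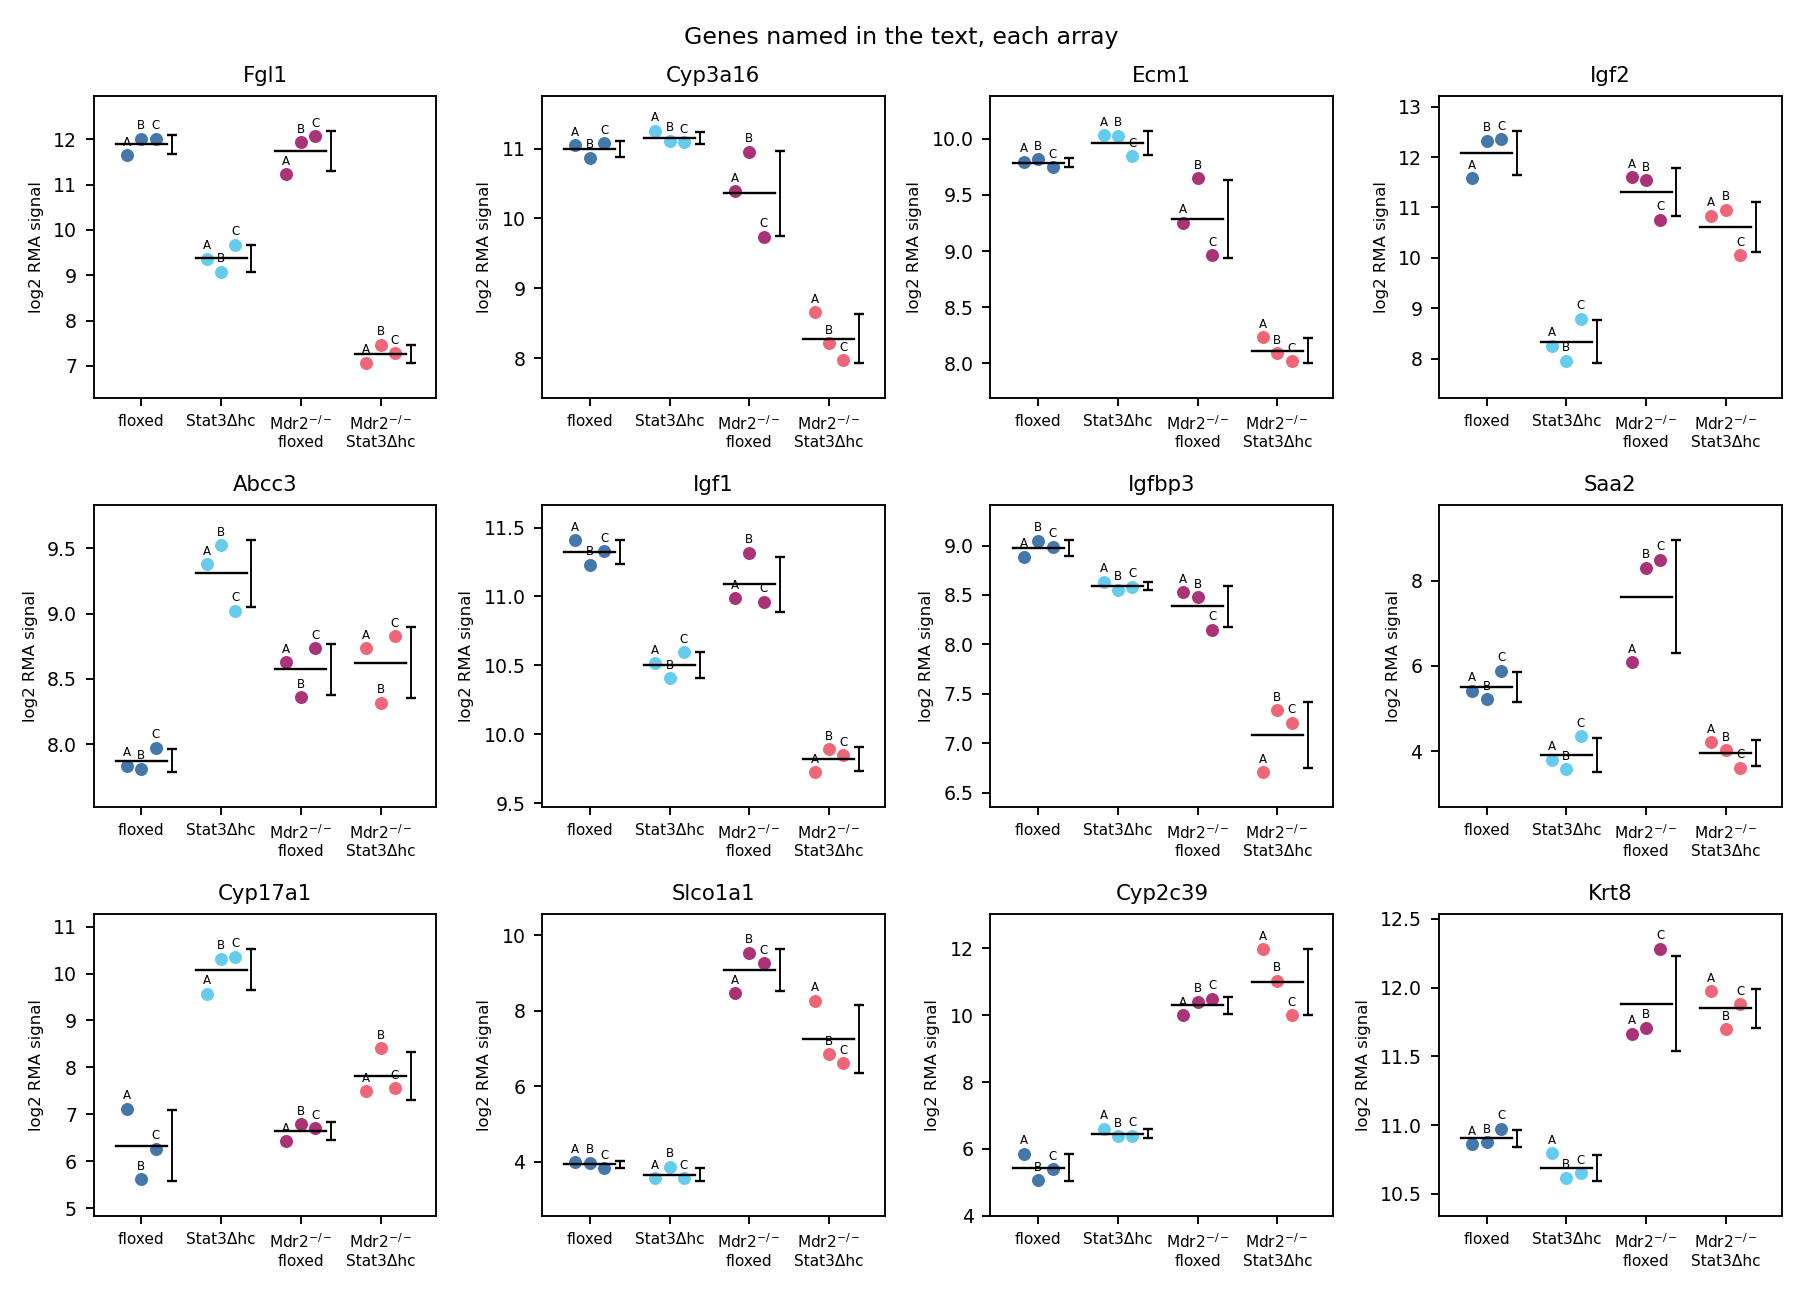
Log2 RMA signal of 12 genes in each of the 12 arrays. Points are arrays with their letters, bars are group means and whiskers are 1 SD (n = 3), and Fgl1 had group means of 11.89, 9.37, 11.75 and 7.27 from left to right.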

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

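The per-array pancreas test, the residual spread of the drawn splits and the fits with the sex pattern as a covariate or with arrays of 1 pattern only were chosen after the result was seen.

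The effect of Stat3 deletion differed between the Mdr2 genotypes by the test of the difference for 10 genes: Abcc3 (-1.38), Ctns (-0.8), Cyp3a16 (-2.23), Cyp4a31 (-1.97), Ecm1 (-1.35), Efemp1 (-0.88), Fgl1 (-1.96), Igf2 (3.06), Olig1 (1.07) and Tenm3 (-0.73). Ctns, Efemp1 and Tenm3 lie outside the rule for named genes and were chosen after their values were seen. With the sex pattern as a covariate 0 of the 10 kept their calls, but with differences of -2.16 for Fgl1, 3.28 for Igf2 and -1.36 for Cyp4a31, of which only the last is clearly smaller, and a median SE of 0.184 against 0.155, the loss does not show that sex accounts for them. Of 100 drawn splits of the 12 arrays, 3 gave as many genes, the real one with 10 included. The draws mix the genotypes, and their median residual SD was 0.153 to 0.191 against 0.137 in the real split, and 91 of them gave 0 genes, so they do not decide whether chance made the result. The highest other draw gave 140 genes, several times the real count, which may reflect a structure of the samples. It kept the 3 Mdr2-/- Stat3Δhc arrays together. Its contrast set them, with floxed B and Mdr2-/- floxed A and C, against the other arrays. Those were Stat3Δhc A, B and C, floxed A and C and Mdr2-/- floxed B. The division thus largely followed the Mdr2 genotype and the traits that go with it. Its count therefore does not bear on whether chance made the difference of the Stat3 effects.

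For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05, and only the real split, 1 of the 10, gave as many genes in each. Every other split mixes the compared genotypes, which shrinks a real difference and adds it to the spread, so their low counts add little. The real counts and the highest of the other splits were 806 and 1 for Stat3 deletion on the Mdr2 knockout, 361 and 3 without it, 1785 and 0 for Mdr2 loss in floxed liver, and 2431 and 0 in Stat3Δhc liver.

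The first pattern is the level of skeletal muscle transcripts in all 6 arrays without the Mdr2 knockout. Over 33 muscle genes outside the ranked lists the smaller fall of the 2 medians was -1.67, with means of 9.58, 9.15 and 8.84 for Tnnc2, Mb and Mylpf in floxed against 6.35, 6.2 and 5.37 in Mdr2-/- floxed liver, but muscle RNA in those samples and any other cause that raises muscle transcripts together would both give this, so the source stays open. Pancreas RNA was first predicted to show medians of -1 or lower, which it did (-1.43 and -2.04), but 2 arrays without the knockout (lowest mean 5.63) lay in the range of the Mdr2-/- arrays (5.45 to 5.86) while their muscle means were 7.21 and 7.44, so pancreas RNA is argued against as the source. Sex is argued against as well, since the median was -1.64 among 3 against 2 Stat3Δhc arrays with the same Y-linked pattern. Whether the tissue was taken differently or the mice differ in their muscle was not tested.

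The second pattern is the division of the arrays by sex. For Mdr2 loss in floxed liver, where sex and genotype fall together, 87.8 percent of 1727 changed genes outside X and Y moved the same way among Stat3Δhc arrays of 1 pattern, against 52.1 percent of unchanged genes, which argues against sex as the whole cause. Their log2 changes there were a median of 0.624 of those in floxed liver. Since the genes were chosen by passing in floxed liver, that choice alone can make their changes elsewhere smaller, so that part of each change stays open. For Stat3 deletion on the knockout, array A lay a median of 0.524 of the way from the floxed mean to arrays B and C. Without each Mdr2-/- floxed array in turn it was 0.51 to 0.535. That met the bound of 0.5 set in advance against sex, but fell short of arrays B (0.936) and C (0.788) judged the same way from the other arrays. The gene sets differed, with 1418 genes for array A, 343 for B and 453 for C. Array A also helped to choose the genes for B and C, so these fractions are not directly comparable. The verdict also required a margin of the SD of B and C (0.104), which was not part of that bound and was not met. With 1 such array sex cannot be told apart. Without array C, 0.485 of the 806 genes stayed called in the same direction, between the bounds set for and against that array as the sole source, and fewer than its 391 genes were shared without arrays B (282) and C (363) of Mdr2-/- floxed or B (316) of Mdr2-/- Stat3Δhc liver, so array C does not stand out, though the question stays open.

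The third pattern is the presence of called genes near Abcb4 on chromosome 5, where passenger DNA of another strain around the knockout could change expression. Of the 100 tested genes nearest to Abcb4, 7 were called in both comparisons of Mdr2 loss, against 886 of 13876 elsewhere, a ratio of 1.1 (Fisher's exact test p = 0.684, odds ratio 1.1, 95% interval 0.43 to 2.38). The ratio met the bound set in advance against this cause, an excess under 2-fold, but that bound took no account of the interval. The interval includes the 2-fold excess predicted for this cause, so it stays open. The genes were Steap4, Abcb1a and Abcb1b, which rose, at places -7, -2 and -1 from Abcb4 in gene order. Cacna2d1, Sema3c, Pmpcb and Tomm7 fell, at places 6, 8, 21 and 33. Most of them thus lay close to Abcb4, and the share over 100 genes can hide a denser stretch there. A narrower stretch was not tested.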

How the results depend on the processing

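The alternatives with the sex pattern as a covariate or with arrays of 1 pattern only were chosen after the data were seen, and the others were planned. In every comparison the covariate rests on array A against arrays B and C of Mdr2-/- Stat3Δhc liver, the only group with both patterns. Unless said otherwise the cause was not tested.

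Stat3 deletion on the Mdr2 knockout changed 806 genes. The count was 2298 with array weights, 230 with only the compared groups (fewer arrays), 37 with the covariate, where the median SE was 0.151 against 0.11, and 15 among the Xist arrays (3 against a single array, assumed to vary like them). It ranged from 302 to 1475 with 1 array left out. Without the knockout it was 361, against 208 with all clusters, 2955 with array weights, 234 among the Y-linked arrays (which include all arrays compared), and 69 to 753 with 1 array left out. Mdr2 loss in floxed liver changed 1785 genes, 102 with the covariate (99 of them shared), and 1105 to 2129 with 1 array left out. In Stat3Δhc liver it changed 2431, against 5830 with array weights, 1541 with only the compared groups, and 1156 to 2613 with 1 array left out.

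The difference of the Stat3 effects held 10 genes. It held 6 with no filter, 6 with all clusters, 23 with trend and robust eBayes, 567 with array weights, 1421 with groups by source name and 6 with the covariate (0 shared), and 0 to 64 with 1 array left out. Grouping by source name turns this contrast, by construction, into the negative sum of the Stat3 effects in both backgrounds, so its count is of another quantity. Array weights gave array A of Stat3Δhc liver a weight of 9.01 and array C of Mdr2-/- Stat3Δhc liver 0.26.

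With the replicate block the counts were 473, 237 and 3 for Stat3 deletion on the knockout, without it, and for the difference, and other counts stayed within 1.5 times. Of 18 pairs of arrays with the same letter, 4 correlated above 0.1 (r from -0.409 to 0.366), and 6 of 12 arrays correlated best with their own letter, so the letters were not taken as pairs.

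With an estimated correlation 0 lists were called in each of the 5 comparisons, where camera had called 8, 13, 7, 8 and 10. With fry, 4 were called for Stat3 deletion on the knockout and 1 for the difference. With the covariate, 3 were called for Mdr2 loss in floxed liver. With 1 array left out the lists numbered 6 to 11, 13 to 17, 4 to 8, 8 to 10 and 7 to 16.

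The correlation of the Mdr2 effects was 0.678, and 0.546 with all clusters. That of the Stat3 effects was 0.354 (jackknife SE 0.209), and 0.186 with all clusters. Il1rn had a log2 change of -0.071 (adjusted p = 0.923) with the covariate, against 0.68 in the fit without it, for Mdr2 loss in floxed liver. Single named genes were not recomputed with all clusters or with groups by source name. Over the other settings, a case being 1 gene in 1 setting, direction and call status stayed the same in 8678 cases. With the direction unchanged, a call was lost in 1067 and gained in 101. The direction changed in 15 cases without a call in either fit and in 1 case with a call. With groups by source name the 806 genes of Stat3 deletion on the knockout all turned their direction, by construction.

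Cyclic loess split Stat3 deletion on the knockout into 466 up and 444 down (261 and 545), and median centring split Mdr2 loss into 673 and 888 (995 and 790) in floxed and 635 and 2052 (964 and 1467) in Stat3Δhc liver.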

Other observations

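STAT3 target and feedback genes were not called as a list with Stat3 deletion on the Mdr2 knockout. Of the 18 tested, 0 passed limma's test and 0 passed adjusted over the list alone. Their median was -0.035 while camera leaned upward, with adjusted p = 0.965 (adjusted p = 0.98 with an estimated correlation). Cholangiocyte markers had a median of -0.1 there, with 2 of 14 falling and 3 adjusted over the list alone, and adjusted p = 0.134 (adjusted p = 0.86 with an estimated correlation). With Mdr2 loss Krt19 of this list was lower, unlike Krt18. Its signals were 6.81, 6.88 and 6.86 in floxed and 6.1, 6.27 and 6.43 in Mdr2-/- floxed arrays. They were 6.7, 7.47 and 6.84 in Stat3Δhc and 6.25, 6.02 and 6.59 in Mdr2-/- Stat3Δhc arrays.

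The heart muscle list (7 genes tested) had median changes of -0.13 and 0.11 with Mdr2 loss in floxed and Stat3Δhc liver, with 1 and 0 falls, unlike the skeletal muscle list.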
